A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

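Ribosome footprints were measured in 4 libraries of budding yeast carrying a tagged Not4: input replicates 1 and 2, collected through a sucrose cushion after RNase I digestion, and Not4 IP replicates 1 and 2, from immunoprecipitated ribosomes. Groups were taken from the protocol characteristic of the labels and replicate numbers from the titles. All 4 libraries carry the same genetic background in the labels, although the design text of the series speaks of more than 1 strain. The RNA extraction text is the same for all 4 and names the immunoprecipitated ribosome even for the inputs, so the protocol characteristic, which differs, was followed.

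The submitters' processing notes name CASAVA 1.8, UMI-tools 1.0.1, Bowtie2 2.2.5, TopHat2 2.1.1 and the genome build sacCer3, and the use of each tool, read-length limits and the rule that assigns a footprint to a codon are not given in the sources used here. The authors deposited, for each library, RPM values per codon position of 6663 coding sequences (3006942 positions), with the codons in the E, P and A sites per the file headers. In each file 100% of the values came out as whole multiples of the value of 1 read, within 0.1 read, so reads could be recovered: 1 read was worth 0.0548 and 0.0574 RPM in input replicates 1 and 2 and 0.0261 and 0.0283 RPM in Not4 IP replicates 1 and 2. The RPM of the deposited positions sum to slightly less than the library total, and 0.00916%, 0.0071%, 0.272% and 0.326% of the totals lie outside the listed positions. A floor of 3 reads corresponds to 0.164, 0.172, 0.0782 and 0.0848 RPM, which covers counting error only. A chi-square test of recovered reads over genes gave 11.6 per degree of freedom between the inputs and 22.6 between the Not4 IP libraries, so no library was a copy of another.

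Gene names and coordinates came from a RefSeq gene table of assembly R64, the same assembly as sacCer3. It matched 5988 of the 6663 coding sequences by systematic name, and the coordinates give whole genes, introns included. In 3 coding sequences codons were missing from the listing. Shared sequence was measured as the share of 27-nucleotide windows found in another coding sequence, rebuilt from the deposited codons. Of the genes tested, 274 share over 20% of their windows and are uncertain, since the handling of reads with several matches is not stated here.

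The tests, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Gene values were RPM summed over each coding sequence, tested as log2(RPM + 1) with limma 3.58.1 (lmFit, eBayes with trend) for genes with a mean of 10 RPM or more over the 4 libraries, at a Benjamini-Hochberg adjusted p of 0.05. Fold changes on this scale understate the change of low genes. Changes relative to the median gene come from the same fit after each library was centred on its median log2 value. Standard errors are those of limma, and SDs are over 2 libraries. The count tests on recovered reads, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, called 3875 and 3711 genes. Adjusted p-values of genes, codons, positions and lists are from limma or camera unless another tool is named.

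Gene lists were cytosolic and mitochondrial ribosomal proteins, mitochondrially encoded genes, translation elongation and termination factors, initiation factors, aminoacyl-tRNA synthetases, ribosome biogenesis, RNA polymerase I and III, Ccr4-Not, mRNA decay, ribosome quality control and stress, proteasome base and lid, proteasome core, ubiquitin conjugation, glycolysis and fermentation, TCA cycle, respiratory chain and ATP synthase, amino acid biosynthesis, ergosterol biosynthesis, chaperones and heat shock, ER translocon and folding, plasma membrane transporters, cell wall and GPI proteins, V-ATPase, histones, nuclear pore and transport, SAGA and TFIID, Gcn4 and uORF-regulated mRNAs, autophagy, and kinesins, tubulin and actin. They were written from general knowledge and tested with camera at a preset correlation of 0.01. Of the 30 lists 29 were tested, since 0 of 16 mitochondrially encoded genes matched a name in the files. The pattern for ribosomal protein names also took in RPP1, and NEW1, CPA1 and LEU4 stand in 2 lists each. UPF1, ARG5,6, NUP59, UBC2, UBC3, DOA10 and YAP2 were not matched under these names. The codon list of low tRNA supply was named for codons ending in G or C but also holds CGA and ATA.

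Codon occupancy was the RPM at a position over the mean RPM of its gene body (without the first 15 and last 5 codons), averaged over the positions of a codon within a gene and then over 3514 genes with a mean of 20 RPM or more and a body of at least 50 codons, and its log2 was tested with limma for 61 sense codons. The files name the codons in the E, P and A sites, so the planned site offsets 1 nucleotide shorter and longer could not be run. Codon optimality was the tRNA adaptation weight, computed from tRNA gene copies and wobble pairing. The copies per anticodon were written from general knowledge, and their sum of 275 equals the nuclear tRNA genes in the reference table. Correlations used 100000 permutations, two-sided. The E-site correlation was added after seeing the data. The 5' share was log2 of the RPM in codons 1 to 50 over the rest, each with 0.5 RPM added, for genes of 150 codons or more with a mean of 20 RPM or more. Position changes were log2 of a position's RPM over that of the gene body, each with 0.5 RPM added, for positions with a mean of 2 RPM or more, and codons of called positions were compared with all tested positions by Fisher's exact test.

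Genes were named by rule: the 12 largest rises and 12 largest falls among called genes whose libraries did not overlap, leaving out unnamed dubious frames, the 2 highest and 2 lowest members of each list, and all Ccr4-Not subunits, RPT1 and RPT2. For codons it took the 5 highest and 5 lowest per site, with CGA and CGG and AGG and ATG and the start and stop codons, and for positions the 10 largest rises and 5 largest falls. The rule gave 141 genes. Calls of the 5' share and of positions were compared with the measured shares, with no RPM added, a check chosen after seeing the data. Genes of the 5' share were named after their values were seen.

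Each step was tested on simulated data built from the mean profile of the 4 real libraries. Both groups shared that profile, most genes were left unchanged, and noise was added per gene and by counting, but not per position. The real groups differ in most genes, so these rates hold for the simulated case only. They do not measure errors caused by the added RPM in the real data. For the gene comparison, limma called 100% of 50 genes changed by a log2 of 1 in each direction, 88% and 92% of those changed by -0.5 and 0.5, and 0.687% of 4076 unchanged genes. For the A site 100% of 6 changed and 1.82% of 55 unchanged codons were called. For the 5' share the test called 53% of 100 genes changed by a log2 of 1, and for positions 99% of 200 changed by a log2 of 2. The changed list was recovered by camera and 0 of 20 unchanged lists were called.

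Alternatives were other pseudocounts, filters, scalings and count tests, the gene body alone, other averages of codons, other measures of optimality, each library left out, and the replicate number as a block. Genes without their highest position and without shared sequence were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, R 4.3.3, and matplotlib 3.10.9 for figures. Footprint lengths and reading frames were not analysed here, since the files give codons.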

Results

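Ribosome footprints, the mRNA fragments that a ribosome shields from nuclease, were sequenced from budding yeast (Saccharomyces cerevisiae) carrying a tagged Not4 (MOT2, YER068W). Not4 is the ubiquitin ligase subunit of the Ccr4-Not complex, which shortens poly(A) tails and takes part in mRNA decay. In the 2 input libraries, RNase I-treated ribosomes had been collected through a sucrose cushion, and in the 2 Not4 IP libraries ribosomes had been immunoprecipitated. The title of the series gives its question, whether Ccr4-Not senses codon optimality on translating ribosomes. The values are RPM, read numbers scaled to a common library total, at 3006942 codon positions of 6663 coding sequences, each position standing for the codon in the ribosomal P site. Reads within coding sequences numbered 18239301 and 17409709 in the input libraries, and 38260941 and 35274638 in the Not4 IP libraries. The 10 genes with most reads took 32.1% and 32.2% of the input reads, against 11.4% and 11.3% of the Not4 IP reads. Footprints were found at 25.1% and 23.6% of all codon positions in the inputs and at 46.2% and 45.8% in the pull-downs. Over genes, the replicates correlated at r = 0.996 in the inputs and 0.997 in the Not4 IP, and libraries of different groups at 0.724 to 0.727. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. No mock pull-down was analysed here, and the groups differ in how ribosomes were collected as well as in the selection for Not4.

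YAK1 (YJL141C), which encodes a protein kinase that acts in the response to nutrient stress, had the largest rise in footprints in the Not4 IP on the log2(RPM + 1) scale, from 119 ± 23.4 RPM in the input to 20654 ± 1090 RPM (mean ± SD, n = 2 each). The Pumilio-family RNA-binding protein gene PUF2 (YPR042C) went from 28.5 ± 4.51 to 3932 ± 26.4 RPM. The nucleoporin gene NUP100 (YKL068W) went from 49.6 ± 4.21 to 4237 ± 47.0 RPM, and WHI4 (YDL224C), for another RNA-binding protein, from 43.2 ± 1.38 to 2869 ± 16.3 RPM. Relative to the median gene, these 4 genes rose by 5.83 ± 0.14, 5.46 ± 0.12, 4.78 ± 0.09 and 4.41 ± 0.07 on the log2 scale (± SE). On the sacCer3 build they lie on chromosome X (147967 to 150390), chromosome XVI (650435 to 653662), chromosome XI (310199 to 313078) and chromosome IV (54397 to 56346). PAC1 (YOR269W), a dynein-targeting factor in nuclear migration, rose by 4.50 ± 0.08 from 4.12 ± 0.221 RPM. The other genes among the 12 largest rises were more uncertain. IRC9 (YJL142C, 5.82) overlaps YAK1 on the same strand and shares 59.7% of its sequence windows with it. The flocculin genes FLO1 (YAR050W, 5.36) and FLO9 (YAL063C, 4.62), which mediate cell adhesion, share 63.5% and 68.3% of their windows with other coding sequences, each other included. The order depends on the 1 RPM added: as a plain ratio of means FLO1 rose 225-fold, from 1.23 RPM, IRC9 183-fold and YAK1 173-fold. In 4 more genes much of the Not4 IP signal sat at 1 codon. The share was 91.8% at codon 23 of YOR302W (4.65), the short upstream reading frame of CPA1, and 77.7% at codon 14 of MTC6 (YHR151C, 4.57). It was 45.7% at codon 437 of the histone deacetylase gene HST3 (YOR025W, 4.03) and 20.8% at codon 174 of YAP5 (YIR018W, 4.85), a transcription factor of iron metabolism. YOR302W has only 25 codons, and codon 23 also held 53.9% of its input reads. Leaving out the first 15 and last 5 codons removes codon 23 and keeps only a few codons. The log2 change was then -0.10 (adjusted p = 0.777), which describes those few codons and is no check of the rise at codon 23.

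The 12 largest falls in the Not4 IP included genes of glycolysis, translation elongation and the ribosome. PGK1 (YCR012W, chromosome III, 137746 to 138996), the phosphoglycerate kinase of glycolysis, went from 20944 ± 1021 RPM in the input to 1932 ± 9.94 RPM. It fell by 5.05 ± 0.09 on the log2 scale relative to the median gene, or 33.0-fold. The translation elongation factor genes TEF1 (YPR080W) and TEF2 (YBR118W), which share 96.0% of their windows and cannot be separated, each stood at -4.79, and the enolase genes ENO2 (YHR174W) and ENO1 (YGR254W), which share 43.7%, at -4.68 and -4.55. The stress protein gene HSP12 (YFL014W) stood at -4.68, from 215.4 ± 6.95 to 24.8 ± 1.34 RPM, and TAL1 (YLR354C), the transaldolase of the pentose phosphate pathway, at -4.29. The remaining 5 of the 12 largest falls were ribosomal protein genes or ribosome-associated: RPS14A (YCR031C) at -4.54, RPP1A (YDL081C) and RPS31 (YLR167W) each at -4.34, STM1 (YLR150W) at -4.32 and RPS12 (YOR369C) at -4.29.

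Of 4409 genes with a mean of 10 RPM or more, 4159 differed between Not4 IP and input on the RPM scale by limma with Benjamini-Hochberg adjustment, 3461 higher and 698 lower (83.2% higher). The median gene itself stood 1.58 log2 units higher in the Not4 IP (2.98-fold), so changes of genes and gene groups are given relative to the median gene of each library. Among the 2089 genes with a mean of 50 RPM or more, 1986 differed. On the relative scale 3796 genes differed, 1850 above and 1946 below (48.7% above), and 996 rose and 1226 fell at least 2-fold. TMM scaling gave 2128 above and 1742 below, edgeR on the recovered reads 2131 and 1744, and DESeq2 1843 and 1868. The scale matters for genes near the median: 998 genes were called in opposite directions on the RPM and the relative scale. Of the named genes near the median, VPH1 (-0.12), LEU2 (-0.14) and HSP30 (-0.13) did not pass with TMM scaling or by edgeR (values with TMM), and COX7 (0.37), QCR10 (0.26), RPN10 (0.26), GCD1 (0.30) and RPL4B (0.30) did. With the median taken over genes of 50 RPM or more, MOT2, NOT3, VPH1, HSP30 and PRE4 moved to its upper side, NEW1 did not pass, and COX7, QCR10, RPN10, GCD1, RPL4B and CAF40 (0.47) did. With a pseudocount of 5 RPM, VPH1 (-0.16) did not pass and COX7 (0.31), RPL4B (0.31), RPN10 (0.23) and GCD1 (0.20) did. Without their highest position RPL4B (0.22) and PRE4 (-0.25) passed, and COX7 (0.28) did in the gene body alone. In 4277 genes the libraries of the groups did not overlap, which chance gives for 33.3% of genes with 2 against 2 libraries.

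Genes for the protein synthesis machinery and for central carbon metabolism had a lower ratio of Not4 IP to input footprints than the median gene. Of 138 cytosolic ribosomal protein genes tested, 135 fell, 1 rose and 2 did not pass (median -3.25), and all 21 genes of glycolysis and fermentation fell (median -3.52), from PGK1 to PFK1 (-2.08) and GLK1 (-2.11). The 1 that rose, RPP1 (0.69), encodes a subunit of RNase P, a tRNA-processing enzyme, not a ribosomal protein. The 2 that did not pass were RPL4A (0.08) and RPL4B (0.15), which share 83.3% of their windows and had 3317 ± 203 and 3342 ± 211 RPM in the input. RPL4B passed without input replicate 2 (0.26, adjusted p = 0.0102). Of 28 chaperone and heat shock genes 27 fell and 1 rose (median -2.99), with ZUO1, a ribosome-bound co-chaperone, at -4.25 and HSP30 at -0.29. HSP42, a small heat shock protein, stood at 0.28 and no longer passed without Not4 IP replicate 1 (0.25, adjusted p = 0.106). All 15 translation elongation and termination factors fell (median -2.22), the smallest falls being NEW1 (-0.57) and RLI1 (-0.73). NEW1 did not pass with the median taken over genes of 50 RPM or more (-0.13, adjusted p = 0.0917). Of 27 initiation factors 22 fell, 1 rose and 4 did not pass (median -2.02), with the poly(A)-binding protein gene PAB1 at -3.48, TIF2 at -3.33 (91.1% shared with TIF1) and TIF4632, an eIF4G gene, at 0.37. GCD1 (0.13) passed without input replicate 1 (0.20, adjusted p = 0.0331). All 20 aminoacyl-tRNA synthetase genes fell (median -2.04), led by GUS1 at -4.03 and SES1 at -2.76, with TYS1 (-1.08) and ILS1 (-1.16) at the other end. All 17 genes of the TCA cycle fell (median -2.11), with MDH1 at -3.44 and KGD2 at -3.27 against SDH3 at -0.83 and SDH2 at -1.07. All 10 histone genes fell too (median -1.98), with HTB1 at -2.98, HTA1 at -2.60, HHF1 at -1.46 and HTZ1 at -1.25.

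Amino acid biosynthesis genes driven by the activator Gcn4 fell in 46 of 47 cases (median -1.81), with MET6 at -3.16 and THR4 at -3.10, and the exception HIS3 stood at -0.21 without passing. HIS3 did pass with a pseudocount of 5 RPM (-0.42, adjusted p = 0.0021) and without its highest position (-0.50, adjusted p = 0.0058), but stood at 0.08 with TMM scaling. LEU2 was at -0.33, and the strain background carries mutant his3 and leu2 alleles. Of 35 nuclear genes for the respiratory chain and ATP synthase 33 fell and 2 did not pass (median -1.80), with COX13 at -3.24 and ATP1 at -3.04. The 2 were COX7 (0.21), which passed without input replicate 2 (0.35, adjusted p = 0.00201), and QCR10 (0.09), which stood at -0.21 without its highest position. Subunits of the vacuolar proton pump (V-ATPase) fell in 14 of 15 cases (median -1.66), with VMA10 at -3.06 and VMA8 at -2.87. STV1, a Golgi form of the membrane subunit, rose by 1.03 and VPH1, its vacuolar form, was at -0.29 and did not pass without Not4 IP replicate 2 (-0.21, adjusted p = 0.0721). Of 25 genes for cell wall and GPI-anchored proteins 21 fell, 3 rose and 1 did not pass (median -1.50), with PIR1 at -3.40 and CIS3 at -3.38 against YPS1 at 0.42 and the glucan synthase gene FKS1 at 0.28. Ribosome biogenesis genes fell in 57 of 69 cases, rose in 7 and did not pass in 5 (median -1.01), with NSR1 at -3.62 and NOP1 at -2.81 against UTP20 at 1.19 and TSR3 at 0.66. Of the TSR3 reads in the Not4 IP 45.5% lay at codon 133, without which it was at 0.02. Of 23 ergosterol biosynthesis genes 16 fell, 2 rose and 5 did not pass (median -0.88), with ERG20 at -2.71 and ERG13 at -2.67 against NCP1 at 0.38 and ERG8 at 0.37.

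These 14 groups were called lower than the other genes by camera with a preset correlation of 0.01, with adjusted p from 9.34e-74 for ribosomal proteins and 7.39e-24 for glycolysis up to 0.00626 for ribosome biogenesis and 0.0162 for ergosterol biosynthesis. None of them passed with a correlation estimated from these libraries. That test keeps only the few degrees of freedom that 2 libraries per group leave. It had little power to call any list, so it cannot decide here. Its adjusted p was 0.173 for ribosomal proteins, glycolysis, the TCA cycle, the respiratory chain, initiation factors and amino acid biosynthesis. For chaperones the adjusted p was 0.212. With an estimated correlation it was 0.398 for elongation factors, 0.435 for tRNA synthetases and histones, 0.441 for V-ATPase and 0.457 for cell wall, ribosome biogenesis and ergosterol genes. Ergosterol biosynthesis also lost its call without Not4 IP replicate 2 (adjusted p = 0.0534). Fry, which asks whether a list moves 1 way on the RPM scale and does not compare it with other genes, called 27 lists. Neither camera nor fry took account of input level or codon optimality, which both correlated with the gene change (rho = -0.621 and -0.669). List membership was therefore not told apart from these. For each of the 29 lists tested, the counts adjusted over the list alone were the same as those over all genes on the relative scale. On the RPM scale the ribosomal protein list still split as 6 higher, the RNase P gene RPP1 among them, and 127 lower. The glycolysis genes split as 0 and 21. The balance was closer for amino acid biosynthesis (16 and 28, median -0.20), the respiratory chain (11 and 18) and initiation factors (10 and 16). Ribosome biogenesis (41 higher, 18 lower, median 0.60), ergosterol (13 and 10, median 0.73), cell wall (12 and 12, median 0.11) and V-ATPase genes (6 and 6, median -0.06) lay near or above no change.

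**Figure D1:**
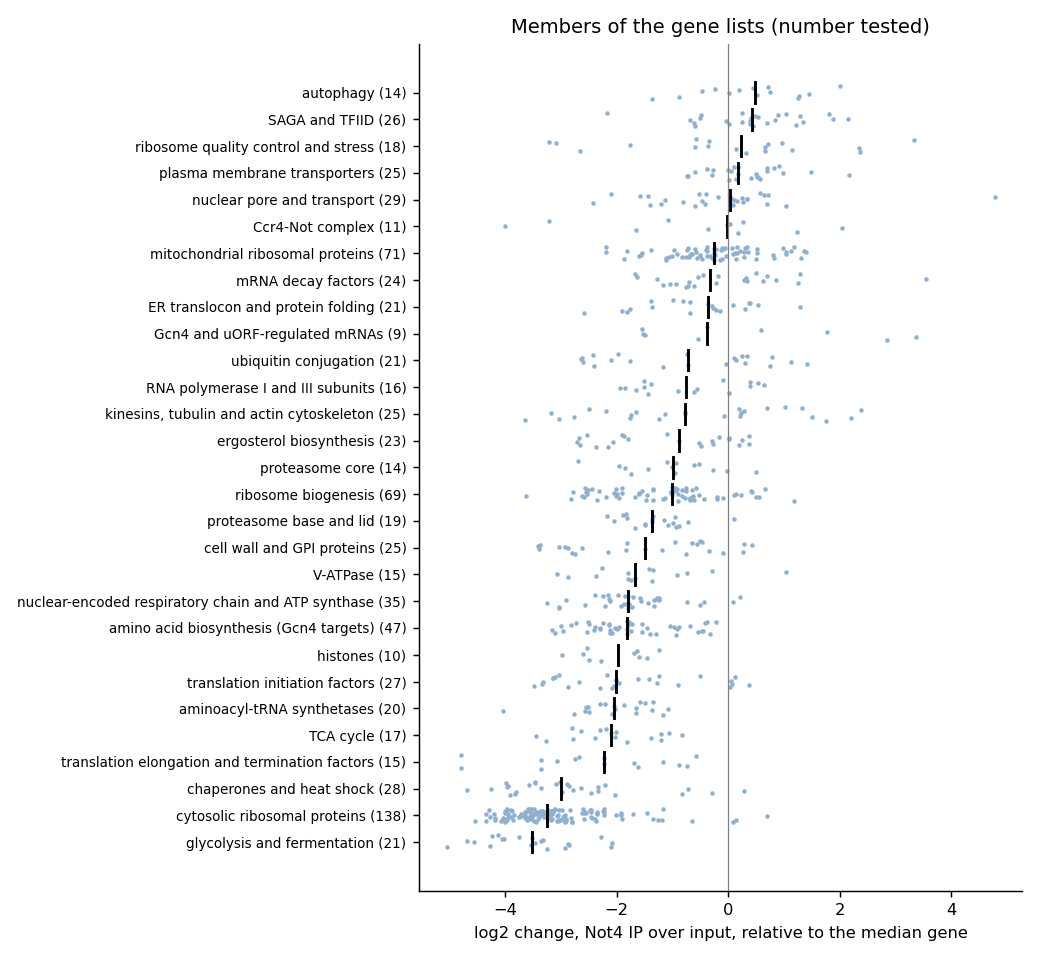
Log2 change of footprints, Not4 IP over input, relative to the median gene (x axis), for every tested member of 29 gene lists fixed beforehand (1 row per list, number tested in parentheses). Each point is 1 gene from the fit over 2 input and 2 Not4 IP libraries, and black bars mark list medians, which run from -3.52 for glycolysis and fermentation to 0.48 for autophagy.

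Plasma membrane transporters were the 1 group called higher than the other genes, and 12 of 25 rose, 5 fell and 8 did not pass (median 0.18). Camera gave an adjusted p = 0.0222 with the preset correlation and an adjusted p = 0.398 with an estimated correlation. The potassium transporter gene TRK1 rose by 1.48 and the arginine permease gene CAN1 by 2.17, though the background carries a mutant can1 allele. The hexose transporter genes HXT6 (-0.74) and HXT7 (-0.72), which share 96.1% of their windows, fell. The group's call was lost without Not4 IP replicate 1 (adjusted p = 0.157), without Not4 IP replicate 2 (0.148), and with median centring (0.155). The autophagy genes (9 of 14 rose, 3 fell, median 0.48) and the SAGA and TFIID subunits, which act in transcription initiation (16 of 26 rose, 6 fell, median 0.43), did not reach a call (adjusted p = 0.175 and 0.0675). Their adjusted p was 0.526 and 0.459 with an estimated correlation. ATG13 rose by 2.00, VPS34 by 1.45, TAF1 by 2.14 and TRA1 by 1.89, whereas ATG8 (-1.37), ATG18 (-0.87), TAF14 (-2.17) and TAF6 (-0.68) fell.

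Several regulatory groups held members far to both sides of the median gene. Among 18 genes of ribosome quality control and stress 9 rose and 8 fell (median 0.23, mean 0.004). SYH1 and SMY2, a pair of related GYF-domain proteins, stood at 3.32 and 2.36 against the ribosome-bound proteins MBF1 (-3.20) and ASC1 (-3.09). Of 24 mRNA decay factors 10 rose and 13 fell (median -0.33), with PUF3, a Pumilio protein of mitochondrial mRNAs, at 3.54 and SKI7 at 1.29 against SCD6 (-1.66) and the ribosome rescue factor DOM34 (-1.62). Of 9 mRNAs of Gcn4 and other genes with upstream reading frames 4 rose and 5 fell, and here the median (-0.38) and the mean (0.34) differ in sign. The activator gene INO2 stood at 3.37 and the cyclin gene CLN3 at 2.85 against LEU4 (-1.54) and HAC1 (-1.53). Of 29 nuclear pore and transport genes 10 rose and 13 fell, with a median of 0.03 and a mean of -0.16, NUP100 at the top, NUP170 at 1.04, and the import factors KAP123 (-2.42) and SRP1 (-2.10) at the bottom. Cytoskeletal genes rose in 10 and fell in 13 of 25 cases (median -0.77), with the formin gene BNI1 at 2.39 and the kinesin gene CIN8 at 2.2 against the actin-binding proteins ABP1 (-3.63) and COF1 (-3.18).

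Mitochondrial ribosomal protein genes split as 18 above, 35 below and 18 not passing of 71 (median -0.26), from MRPL20 (1.40) and MRPL3 (1.36) to MRPL40 (-2.20) and MRP8 (-2.19). ER translocon and folding genes gave 5 above and 12 below of 21 (median -0.36), with JEM1 at 1.28 and SEC61 at 0.54 against SSS1 (-2.59) and SBH1 (-1.91). Ubiquitin conjugation genes gave 6 above and 11 below of 21 (median -0.71), with DOA4 at 1.41 and TOM1 at 1.12 against UBP6 (-2.64) and RAD6 (-2.63). RNA polymerase I and III subunits gave 4 above and 10 below of 16 (median -0.76), with RET1 at 0.64 and RPA190 at 0.53 against RPA49 (-1.93) and RPC19 (-1.86). Proteasome base and lid genes fell in 18 of 19 cases (median -1.36), with RPT5 at -2.17, RPT6 at -2.04, RPN12 at -0.72 and RPN10, which did not pass, at 0.10. RPN10 passed without input replicate 2 (0.17, adjusted p = 0.0444). The proteasome core gave 1 above, 12 below and 1 not passing of 14 (median -0.98), with PRE2 at -2.69, PRE8 at -1.96, PUP3 at 0.49 and PRE4 at -0.02. On the RPM scale, where the median gene stood higher, each group of this paragraph and the one before had more members higher than lower. Mitochondrial ribosomal protein genes split as 63 higher and 2 lower, ER genes as 16 and 1, and ubiquitin conjugation genes as 13 and 7. The split was 11 and 5 for base and lid, 9 and 3 for the core, 22 and 0 for mRNA decay and 26 and 2 for nuclear pore genes. Camera called none of the groups in this paragraph or in the one before it. Its adjusted p ran from 0.0909 for the base and lid of the proteasome to 0.962, and from 0.459 to 0.978 with an estimated correlation. The base and lid group was called without input replicate 2 (adjusted p = 0.0351) and, with median centring, so were base and lid (8.32e-05) and core (0.00737). Camera's direction was up, against medians below 0, for mRNA decay factors, mitochondrial ribosomal proteins and the Gcn4 group, and down, against a median above 0, for none.

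The mRNAs of the Ccr4-Not subunits did not move together in the Not4 IP. MOT2 itself, encoding the tagged protein (chromosome V, 293050 to 294813), went from 39.9 ± 1.46 RPM to 96.1 ± 3.66 RPM. It stood higher on the RPM scale (log2 change 1.25) but below the median gene (-0.36 ± 0.08, adjusted p = 0.00169). CAF130 (YGR134W), encoding an accessory subunit, rose by 2.05 ± 0.14 and CDC39 (YCR093W), which encodes the scaffold Not1, by 1.23 ± 0.06. NOT5 (YPR072W), whose protein contacts the ribosome, fell by 1.09 ± 0.11 and CDC36 (YDL165W), Not2, by 1.65 ± 0.10. The deadenylase genes POP2 (YNR052C) and CCR4 (YAL021C) stood at 0.26 ± 0.07 and 0.18 ± 0.06 (adjusted p = 0.00888 and 0.0247), and CAF40 (YNL288W, 0.03) and NOT3 (YIL038C, -0.03) did not pass. EGD2 (-4.0) and EGD1 (-3.21), subunits of the nascent chain-associated complex, a ribosome-bound chaperone and Not4 substrate, had the lowest values of the list. Of the 11 list members tested, EGD1 and EGD2 included, 4 lay above and 5 below the median gene (median -0.03, mean -0.60, camera adjusted p = 0.681, adjusted p = 0.719 with an estimated correlation). EGD1 and EGD2, which belong to another complex, pull the mean down. On the RPM scale 8 of the 11 members were higher and 2 lower. CCR4 lost its call with a pseudocount of 0.1 RPM (0.15, adjusted p = 0.0582), by DESeq2 (0.16, adjusted p = 0.0832), without input replicate 1 (0.15, adjusted p = 0.0545), without Not4 IP replicate 1 (0.19, adjusted p = 0.0984) and without Not4 IP replicate 2 (0.17, adjusted p = 0.15). MOT2 was not called by edgeR (-0.19, adjusted p = 0.0553) and stood at 0.08, above the median, when only genes with a mean of 50 RPM or more were used. The proteasome subunit genes RPT1 (YKL145W) and RPT2 (YDL007W) fell by 1.81 ± 0.08 and 1.68 ± 0.09 relative to the median gene. Their levels were 138 ± 3.78 against 120 ± 5.49 RPM and 97.7 ± 11.5 against 92.9 ± 7.96 RPM.

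Genes with poorly adapted codons had more footprints in the Not4 IP, relative to the input, than genes with well adapted codons. Codon optimality was taken as the mean natural log of the tRNA adaptation weight, a measure of how well the tRNA pool decodes a codon. With genes ranked by optimality and parted into 5 groups, the median change relative to the median gene, from the least to the most optimal group, was 0.87, 0.75, 0.15, -0.62 and -2.09 (881 or 882 genes each). Ribosomal protein and glycolysis genes lay at the optimal end, and YAK1, PUF2 and NUP100 towards the other. Across 4408 genes the change correlated with codon optimality at Spearman's rho = -0.669 and Pearson's r = -0.697, and rho was -0.639 without the ribosomal protein genes. In the same family of 5 relations, rho was 0.402 for coding length, -0.278 for GC content, 0.348 for the share of asparagine and glutamine in the protein and -0.621 for the input level. The input level is itself subtracted to give the change, so the 2 are tied by construction and that rho cannot be read like the others. Each p of 1e-05, before and after adjustment over the 5, is the smallest that 100000 permutations can give, and genes are not independent replicates.

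**Figure D2:**
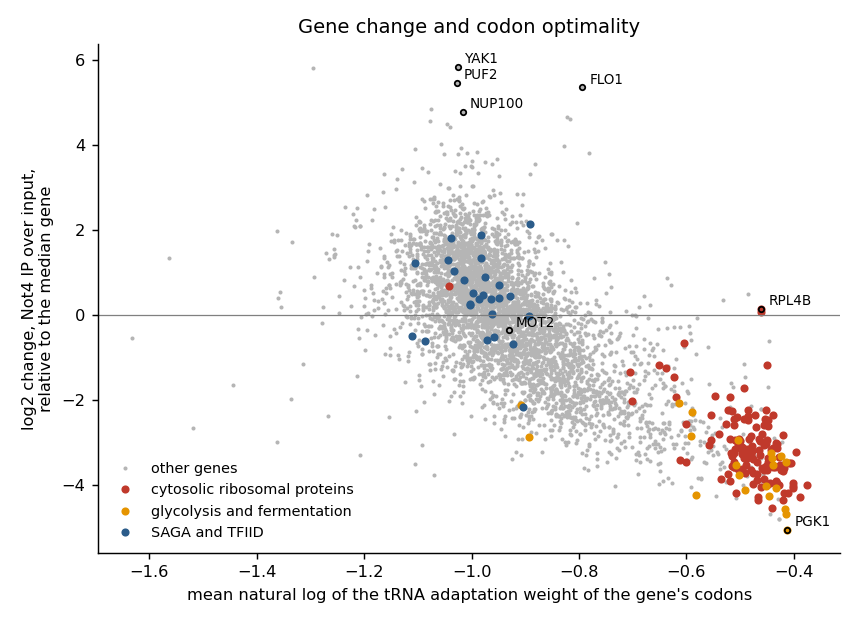
Log2 change of each of 4408 genes, Not4 IP over input, relative to the median gene (y axis), against the mean natural log of the tRNA adaptation weight of its codons (x axis). Colours mark genes for cytosolic ribosomal proteins, glycolysis and fermentation, and SAGA and TFIID, black circles mark named genes, and the change falls as optimality rises (rho = -0.669).

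Ribosomes in the Not4 IP had more often a CGA codon, an arginine codon read by an inosine-containing tRNA, waiting in the A site, where the next tRNA enters. Relative occupancy, the RPM at a codon over the mean of its gene body averaged over 3514 genes, was 1.12 ± 0.00333 for CGA in the input and 3.95 ± 0.0285 in the Not4 IP (mean ± SD, n = 2), a 3.52-fold rise (log2 change 1.82, and 1.03 with positions capped at 10 times the gene mean). The leucine codon CTG rose from 1.26 ± 0.0320 to 2.60 ± 0.00564, the arginine codon CGG by 0.86 on the log2 scale, the proline codon CCG by 0.71 and the serine codon TCG by 0.42. The largest falls were in the leucine codon CTC (-0.59), the glycine codon GGC (-0.44) and the tyrosine codon TAT (-0.37). The isoleucine codon ATT (-0.33) and the valine codon GTA (-0.31) followed. Of the 61 sense codons 18 rose and 34 fell by limma, with a standard error of 0.034 for each. The methionine codon ATG fell by 0.20. The arginine codon AGG, at 0.03, did not pass (adjusted p = 0.378), although it rose by 0.46 when positions were weighted by expression (adjusted p = 0.00385) and by 0.20 among genes with a mean of 100 RPM or more. GTA did not pass with weighting by expression (-0.14, adjusted p = 0.406).

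In the P site, which holds the tRNA carrying the nascent chain, the changes were larger and led by leucine codons that begin with CT. CTG rose from 1.21 ± 0.0584 to 4.0 ± 0.00383 (3.32-fold) and CTA from 1.15 ± 0.0134 to 3.11 ± 0.0861, followed by the serine codons TCG (log2 change 1.22) and AGT (1.15) and the isoleucine codon ATA (1.12). CTT was at 1.08, CGA at 1.04, AGG at 0.93 and CGG at 0.24. The asparagine codons AAC (-0.73) and AAT (-0.66), the valine codon GTC (-0.63), the alanine codon GCC (-0.57) and the histidine codon CAC (-0.57) had the largest falls, and ATG fell by 0.36. By amino acid, the mean P-site change was highest for leucine (0.75), serine (0.58), cysteine (0.56) and glutamine (0.53) and lowest for asparagine (-0.70). The leucine codons went both ways: CTC rose by 0.43, while TTA fell by 0.14 (adjusted p = 0.00124) and TTG, at -0.01, did not pass (adjusted p = 0.615). Of 61 codons 23 rose and 36 fell, but 26 rose and 27 fell with weighting by expression. The median codon change was -0.32, and -0.05 with that weighting. Occupancy is relative to the gene body at each site, so rises at some codons lower others. Part of the falls may follow from this alone. The size of the rises depended on very high positions: 7 codons rose at least 2-fold, against 4 with weighting by expression and 1 with positions capped at 10 times the gene mean. With this cap CTG stood at 1.16 and CTA at 0.98 in the P site. CGG lost its call without Not4 IP replicate 1 (0.18, adjusted p = 0.0950) and among genes with a mean of 100 RPM or more (0.11, adjusted p = 0.234).

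In the E site, which holds the departing tRNA, changes were smaller, and fewer codons passed with 1 library left out. CTT rose by 0.50, the arginine codons CGC, CGA and AGG by 0.48, 0.46 and 0.41, and CCG by 0.37. AAT (-0.39), the cysteine codons TGC (-0.29) and TGT (-0.27), the histidine codon CAT (-0.26) and the phenylalanine codon TTT (-0.25) fell. In total 22 codons rose and 17 fell, but 13 rose and 22 fell with positions capped at 10 times the gene mean, and 29 codons passed without input replicate 1, 30 without input replicate 2 and 23 without either of the Not4 IP replicates. AGG kept its size but did not pass without input replicate 1 (0.40, adjusted p = 0.0567) and input replicate 2 (0.41, adjusted p = 0.0562). The same held for ATG (-0.16) without Not4 IP replicate 1 (-0.17, adjusted p = 0.0581) and Not4 IP replicate 2 (-0.16, adjusted p = 0.0714). CGG (0.23) did not pass without input replicate 1 (0.27, adjusted p = 0.0994), input replicate 2 (0.18, adjusted p = 0.192) and Not4 IP replicate 1 (0.15, adjusted p = 0.109). With weighting by expression CCG stood at -0.09. Over distances from the P site, the standard deviation of the 61 codon changes was 0.620 in the P site, 0.381 in the A site and 0.205 in the E site. It was 0.358 and 0.309 at 4 and 5 codons upstream of the P site, near the 5' end of the footprint.

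**Figure D3:**
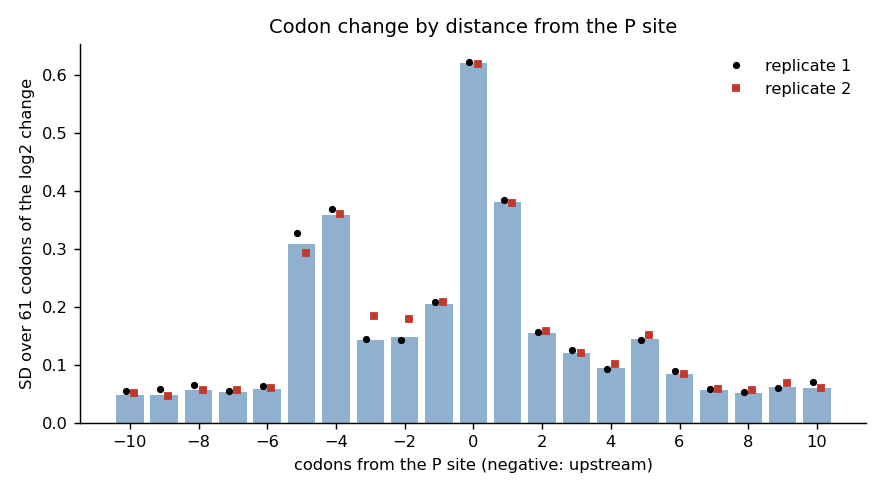
Standard deviation over 61 codons of the log2 occupancy change, Not4 IP over input (y axis), with the codon at each distance from the P site (x axis, codons, negative upstream). Bars give the change of the group means and points each replicate number alone, and the bars reach 0.620 in the P site, 0.381 in the A site (distance 1) and 0.358 at distance -4.

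Among the codon lists fixed beforehand, 1 was named for arginine codons read by rare tRNAs and held CGA, CGG and AGG. The name does not suit CGA, since the inosine-containing tRNA that reads it also reads CGT and has 6 gene copies. All 3 codons rose in the P site and in the E site (medians 0.93 and 0.41) and 2 of 3 in the A site (0.86). Of 12 codons with low tRNA supply 7 rose and 3 fell in the A site (median 0.20), 9 rose and 3 fell in the P site (0.50), and 8 rose and none fell in the E site (0.18). The 4 proline codons split as 3 up and 1 down in the A site (0.13), 1 up and 3 down in the P site (-0.31) and 4 up in the E site (0.27). Of the 4 codons for acidic residues 0 rose and 2 fell in the A site (-0.14), 4 fell in the P site (-0.52), and 2 rose and 1 fell in the E site (0.06).

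Occupancy gains in the Not4 IP went with low tRNA adaptation at each of the 3 sites, with exceptions such as CTC, which fell in the A site. Across the 61 codons the change correlated with the tRNA adaptation weight at rho = -0.593 and r = -0.567 in the P site (p = 1e-05, the smallest these permutations can give, adjusted p = 3e-05 for each). In the A site rho was -0.437 (p = 0.00041, adjusted p = 0.000615) and r was -0.423 (p = 0.00058, adjusted p = 0.00087). In the E site rho was -0.369 (p = 0.0035, adjusted p = 0.0035) and r was -0.343 (p = 0.00675, adjusted p = 0.00675). Adjustment was over the 3 sites, tests were two-sided permutation tests, and codons are not independent replicates. Without the 2 codons farthest from the median weight, both of high weight, r was -0.585, -0.461 and -0.349 in the P, A and E sites. The low-weight codons CGA and CTG were kept, so their influence was not checked in this way. Outside the 3 sites rho reached -0.270 at 5 codons upstream of the P site, and 0.294 and -0.288 at 6 and 7 codons downstream. The E-site value is not far beyond these. The changes at the 3 sites also correlated with each other (rho = 0.508 for P and A, 0.446 for A and E, 0.341 for P and E). The 3 correlations are therefore not separate evidence. In the input alone, occupancy itself correlated with the weight at rho = -0.266 in the P site and -0.289 in the A site. With the number of tRNA gene copies of the cognate anticodon in place of the weight, rho was -0.205 in the P site (adjusted p = 0.171), -0.303 in the A site (0.0549) and -0.110 in the E site (0.395). With weighting by expression it was -0.246 in the E site (0.0556).

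**Figure D4:**
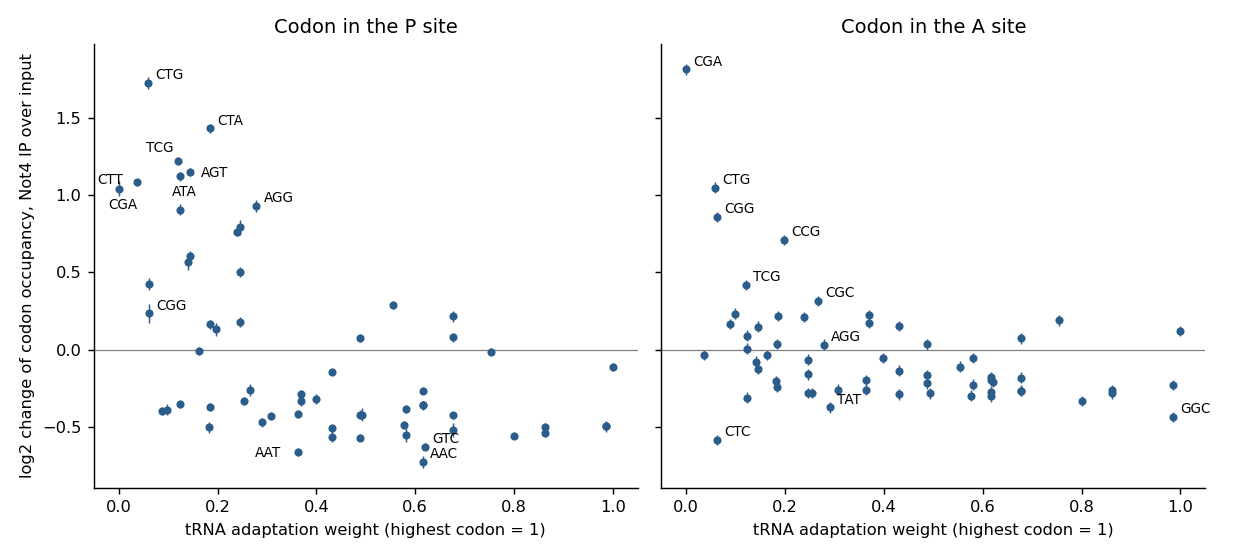
Log2 change of codon occupancy, Not4 IP over input (y axis, bars show the SE, n = 2 libraries per group), against the tRNA adaptation weight of the codon (x axis, highest codon set to 1), for the P site (left) and the A site (right). Codons of low weight lie highest, with CTG at 1.73 in the P site and CGA at 1.82 in the A site.

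Stop codons in the A site, where release factors act, had a higher mean occupancy in the Not4 IP. Relative occupancy was 0.284 ± 0.002 in the input and 0.578 ± 0.006 in the Not4 IP (mean ± SD, n = 2), a ratio of 2.03. The ratio was 2.36 for TGA, 2.14 for TAG and 1.74 for TAA. Codons 2 to 15 of the coding sequence had 0.213 ± 0.019 against 0.328 ± 0.008 (1.55-fold). Part of this came from 1 gene: the ratio was 1.34 without MTC6 and 1.32 without codon 14, 2 omissions chosen after the values were seen. The start codon in the P site had 0.459 ± 0.046 against 0.517 ± 0.016, and the 4 to 6 codons before the stop codon 1.62 ± 0.043 against 1.86 ± 0.017. These start and stop features were not tested.

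Within genes, the share of footprints in the first 50 codons shifted in both directions. It rose in CAF20 (YOR276W), encoding an eIF4E-binding protein, from 2.78% ± 1.0 to 21.5% ± 3.84 (SD, n = 2), and in GOS1 (YHL031C), a Golgi SNARE, from 7.62% ± 0.703 to 43.5% ± 1.28. It went in MTC6 from 36.9% ± 0.804 to 84.6% ± 2.71 and in ARG4 (YHR018C), of arginine synthesis, from 2.07% ± 0.220 to 14% ± 0.136. It went in the septin gene CDC10 (YCR002C) from 5.99% ± 1.84 to 32.0% ± 0.870 and in NOP13 (YNL175C) from 3.42% ± 0.641 to 22.1% ± 6.18. These 6 were singled out after their values were seen. Of 3249 genes, limma called 351 higher and 1331 lower in the Not4 IP (median log2 change -0.42) on the tested ratio, which has 0.5 RPM added to the window and to the rest of the gene. The measured share rose in 349 of the 351 but fell in only 1055 of the 1331, and in 276 of the latter it did not fall. FLO9, FLO1, FLO5 and MMS22, called lower, had no reads in this window in either input library and some in the Not4 IP. The call is then made by the added 0.5 RPM, which weighs more in genes with low input. The median share was 4.49% and 4.43% in the inputs and 4.34% and 4.38% in the pull-downs. With the reads of all tested genes pooled, the share was 6.86% and 6.67% in the inputs and 5.04% and 5.17% in the pull-downs. The count moved with the pseudocount, to 276 higher and 488 lower with 0.1 RPM in place of 0.5 and to 344 and 2027 with 2 RPM. It was 375 and 724 with a window of 100 codons, and 523 of 1105 genes passed at a mean of 100 RPM or more.

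Of the 10 codon positions with the largest rise relative to their gene, 9 had a leucine codon in the P or A site. Each of the 10 had a limma adjusted p of 0.000338 or less. This leucine count was not set against that of all tested positions. All 10 lay in genes that fell relative to the median gene (-2.63 for RPL6B to -4.0 for RPP2A). The 5 largest falls lay in genes that rose (1.66 to 1.87), and the gene's own change enters each of these values. Several of the 10 lay at codons 4 to 11, although only 760 of 69776 tested positions lay in the first 15 codons. In the ribosomal protein gene RPS4A (YJR145C), codon 9, with CTA in the P site, went from 0.629 to 65.7 RPM (log2 change 7.74 ± 0.51 relative to the gene). Its near copy RPS4B (YHR203C), sharing 63.9% of windows, went from 0.470 to 18.5 RPM at the same codon. Codon 7 of SPI1 (YER150W), a cell wall protein gene, went from 0.563 to 18.6 RPM with CTC in the P site and CTT in the A site, and codon 4 of HSP10 (YOR020C) from 0.168 to 5.0 RPM with CTT in the P site. With CTA in the P site, codon 173 of RPL6B (YLR448W) went from 0.658 to 25.5 RPM and codon 93 of EGD1 (YPL037C) from 2.75 to 47.2 RPM. Codon 11 of CAF20, with CTG in the A site, went from 0.0561 to 11 RPM on 1 read in each input library. Codon 77 of TMA10 (YLR327C) went from 0.0287 to 9.99 RPM on 0 and 1 reads, and codon 4 of the thioredoxin gene TRX2 (YGR209C) from 1.06 to 26.4 RPM. In RPP2A (YOL039W) the position was codon 106, the last before the stop codon. The largest falls relative to the gene were at codons 19 and 18 of YDR278C, an open reading frame of unknown function. They were followed by codon 35 of 3 Ty1 elements with sequence shared almost in full (YLR157C-B, YER138C and YDR261C-D), from 3.61 to 0.437 RPM in each. Of 69776 positions tested in 3340 genes, 10572 were higher and 16548 lower relative to their gene by limma. The measured share of the gene body, with no RPM added, rose at 10568 of the higher but fell at only 14299 of the lower positions. The calls numbered 15885 in all without Not4 IP replicate 1 and 15215 without Not4 IP replicate 2. The excess of lower positions depended on the settings: it was 10088 higher and 10128 lower with a pseudocount of 0.1 RPM, 15924 and 26492 with 2 RPM, and 5523 and 6373 at a mean of 5 RPM or more. The total also moved with the minimum level (11896 of 29548 positions at 5 RPM, 51574 of 124205 at 1 RPM) and to 42416 with a pseudocount of 2 RPM. Among positions with CTG in the P site 51.0% were higher, against 14.9% of all tested (Fisher's exact test, odds ratio 6.27), followed by CTA (46.8%, 5.30) and CTT (42.1%, 4.3). In the A site CTG (44.4%, odds ratio 4.70), CGA (37.7%, 3.49) and CCG (24.2%, 1.85) led. In the E site CGC (26.5%, 2.07) and CTT (25%, 1.93) led, and GGA in the A site was over-represented among lower positions (53.6% against 23.8%, 3.72).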

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

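Alternatives without the highest position of each gene, without shared sequence and all those of the E-site correlation were chosen after seeing the data. Offsets 1 nucleotide shorter and longer were not run. With 1 library left out, limma assumes that the lone sample varies like the other group. Depth limits single positions: 1 read is worth 0.0548 and 0.0574 RPM in the inputs against 0.0261 and 0.0283 RPM in the Not4 IP.

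The correlation of gene change with codon optimality kept its direction and its side of the threshold under every alternative run for it, from -0.803 to -0.589, and from -0.670 to -0.667 with libraries left out. The count of changed codons stayed within 45 to 53 in the A site and 53 to 59 in the P site. In the E site it was 33 to 41 with other settings but 23 to 30 with 1 library left out, where fewer samples are tested, and with positions capped at 10 times the gene mean more codons fell (22) than rose (13), against 17 and 22. With tRNA gene copies in place of the tRNA adaptation weight, rho no longer passed in the A site (-0.303), the P site (-0.205) or the E site (-0.110), nor did it in the E site with weighting by expression (-0.246). The cause was not tested. In the other alternatives the 3 correlations kept their direction and passed. With libraries left out they ran from -0.601 to -0.589 in the P site, -0.449 to -0.416 in the A site and -0.408 to -0.356 in the E site.

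The split of genes into higher and lower followed the scale by construction: on the RPM scale 3461 were higher and 698 lower, against 1850 and 1946 when median centred, 2128 and 1742 with TMM scaling, 2131 and 1744 by edgeR, and 1843 and 1868 by DESeq2. With a mean of 50 RPM or more, where fewer genes are tested (2089), 1986 differed and 1416 were higher. That filter also moves the median gene, so MOT2 (0.081), NOT3 (0.41), VPH1 (0.16), HSP30 (0.15) and PRE4 (0.42) came to lie above it. YOR302W turned to -0.10 in the gene body only, and QCR10 to -0.21 without its highest position, each by the reads left out. Of 141 named genes 18 changed call or direction under some alternative. Over single genes, values under the alternatives kept direction and call in 1897 cases, lost the call in 17 and gained it in 31, and for single codons in 367, 10 and 2. The E-site codon CCG turned to -0.088 with weighting by expression, cause not tested.

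The count of changed lists was 0 with an estimated correlation and 27 by fry. With 2 libraries per group the estimated correlation leaves camera few degrees of freedom, so it had little power to call any list. Fry tests direction on the RPM scale and not against other genes. By this construction it turned upward Ccr4-Not (adjusted p = 0.00129), cell wall (0.0503), ER (0.00114), ergosterol (0.00306), cytoskeleton (0.000911), proteasome base and lid (0.0314), proteasome core (0.00381), ribosome biogenesis (0.00488), RNA polymerase I and III (0.000691), ubiquitin conjugation (0.00199) and V-ATPase genes (0.786).

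The count of genes with a changed 5' share fell from 1682 to 1099 with the first 100 codons, 764 with a pseudocount of 0.1 and 523 with a mean of 100 RPM or more, where fewer genes are tested, and was 1265 to 1695 with libraries left out. Changed positions numbered 11896 at a mean of 5 RPM or more (fewer tested), 51574 at 1 RPM (more tested), 42416 with a pseudocount of 2, and 15215 to 25201 with libraries left out. The measured 5' share, with no RPM added, did not fall in 276 of the 1331 genes called lower, against 33 of 488 with a pseudocount of 0.1 and 724 of 2027 with 2. The cause of the window effect was not tested. The comparison of calls with measured shares was chosen after seeing the data.

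With replicate numbers as a replicate block, 4181 genes, 14 lists, 53, 59 and 41 codons (A, P and E sites), 1663 genes by 5' share and 31471 positions passed. The plasma membrane transporters lost their call (adjusted p = 0.153) and COX7 gained one. The numbers are all that pairs the samples: deviations of replicate 1 from its group mean correlated between the groups at 0.0919 over genes, 0.257 over A-site, 0.327 over P-site and 0.328 over E-site codons.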

Other observations

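The genes in this paragraph and the next were named after their values were seen, and the tests of footprints assigned 1 codon off, of a few positions with very many footprints and of more footprints on asparagine and glutamine codons were also chosen after the result was seen. Some related genes lay far apart in the Not4 IP, while others in the report lay close together, such as SYH1 and SMY2. Among Pumilio-family genes, which encode RNA-binding proteins, PUF2 rose by 5.46 on the log2 scale relative to the median gene, JSN1 by 3.66 (from 67.1 to 2622 RPM) and PUF3 by 3.54, against 1.44 for PUF4 and 1.27 for MPT5. PUF6 fell by 1.78. WHI4 rose by 4.41 and WHI3, its relative, by 1.76 (from 47.8 to 503 RPM). The nucleoporin genes NUP100 and NUP116 rose by 4.78 and 0.71 (NUP116 from 71.9 to 362 RPM). FLO5, which shares 41.9% of its sequence windows with FLO1, rose by 3.99.

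CPA1, of arginine synthesis, fell by 0.38, while its upstream reading frame YOR302W stood at 4.65 with 91.8% of its Not4 IP reads at codon 23. The ribosomal protein genes RPL4A (0.08) and RPL4B (0.15) stood near the median gene, whereas RPL3 fell by 2.45.

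Changes of codon occupancy were larger in the P site than in the A site. Assignment of the Not4 IP footprints 1 codon off is argued against, since the start-codon peak stood at the same codon as in the inputs and was 3.35 and 3.46 times its higher neighbour in the Not4 IP libraries (4.17 and 4.71 in the inputs). A few positions with very many footprints are argued against too: with each position capped at 10 times its gene mean, the SD over codons in the P site was 1.84 times that in the A site. Sequence bias at the ends of footprints stays open, since the SD 4 codons upstream was 0.578 of that in the P site, between the 2 bounds set beforehand. For the other sites it stays open as well. The SDs 4 and 5 codons upstream (0.358 and 0.309) were above that in the E site (0.205), and the first came near that in the A site (0.381). The difference between a sucrose cushion and a pull-down also stays open and was not tested.

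Genes of low codon optimality had more footprints in the Not4 IP. Input level is argued against as the whole cause by a rank correlation of -0.456 (SE 0.014) with it held constant, and GC content and length by -0.689 (SE 0.008). Codon occupancy changes are relative to the gene body, so a change shared by a whole gene is not in them. Summed over the gene, they gave a predicted change with an SD of 0.114 of the measured SD. The prediction still correlated with the measured change (rho = 0.703). The small SD argues only against codon changes of the measured size, summed in this way, as the whole cause. Selection of ribosomes on such mRNAs by Not4 may contribute, as a hypothesis, but the collection of ribosomes differs between the same groups, was not tested and stays open.

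Genes for proteins rich in asparagine and glutamine also had more Not4 IP footprints: the 441 genes with the highest share stood at a median of 0.69, against -0.10 for the other 3967. More footprints on the asparagine and glutamine codons themselves are argued against, since the difference between these medians kept 0.956 (SE 0.051) of its size without all positions that had such a codon in the E, P or A site. In the P site the glutamine codons CAA (0.29) and CAG (0.76) rose and the asparagine codons AAT (-0.66) and AAC (-0.73) fell. Low codon optimality and length of these genes may account for part of the pattern. The rank correlation went from 0.348 to 0.177 (SE 0.015) with both held constant. It was 0.195 (SE 0.015) with input level held constant too. The value of 0.177 lies between the bounds set beforehand, so it cannot tell whether optimality and length are the whole cause, and their share stays open. Stickiness of the nascent proteins in the pull-down is a further hypothesis that was not tested, and no mock pull-down was analysed.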
